A study of Homo sapiens with 6 samples.

How the data were processed

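Bulk RNA sequencing of the MV4;11 line was analysed in 6 libraries, 3 control and 3 treated with 10 µg/ml FKA for 48 h, grouped by the titles and treatment labels. Per the labels, total RNA was extracted with a commercial kit. The aligner, the counting tool, the annotation, the library kit and the use of strand are not given in the sources used here. The submitters' processing notes list GRCm38 and mm10, which are names of mouse genome builds, while the gene symbols of the tables are human: 20649 of the 21857 symbols (94.5%) matched the human RefSeq gene table. These symbols argue against a mouse annotation behind the counts. Which build was used remains open and no coordinates are printed. Without a stated use of strand, reads of overlapping and antisense genes cannot be told apart.

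The authors deposited a table of whole-number read counts per gene and a table of FPKM values, each with 21857 genes and 6 columns named by group and replicate. No row named anything other than a gene, and no row was at 0 in all libraries. The deposited FPKM of a gene equalled its count divided by the column total and by 1 length per gene, with a largest relative deviation of 6.9e-07, so both tables hold the same measurements. Count totals ran from 29971171 to 36362421 per library. The replicate pairs of each group differed by far more than counting noise (chi-square per degree of freedom between 23.3 and 71.2), so no library was a copy of another.

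Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (13531 genes, holding at least 99.94% of counts in each library), scaled by TMM and tested with the quasi-likelihood F test of FKA against control, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. At least 2-fold means a fitted log2 fold change of at least 1 either way. The biological coefficient of variation was 15.4%. Levels are TMM-scaled CPM with SD over 3 libraries. Ratios of genes with few counts have exact 95% intervals of the counting error, and for groups at 0 a floor of 3 counts over the group was used.

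The batch label equals the replicate number, so by the labels each control library shares a batch with 1 FKA library. The correlation of deviations from the group means within batches 1, 2 and 3 was 0.05, 0.35 and -0.08. The test was run without the batch, and again with the batch as a block.

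42 gene lists were fixed before the data were examined and 41 of them, with at least 3 tested genes, were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. They cover the genes of the study's title, replication licensing and fork, G1/S, G2/M, G1 cyclins, CDK inhibitors, CUL4 and SCF ligases, p53 targets, the BCL2 family, NRF2 targets, ATF4 targets, endoplasmic reticulum chaperones, heat shock, sterol and fatty acid synthesis, AHR targets, MYC and ribosome biogenesis, ribosomal proteins, nuclear and mitochondrial respiratory genes, glycolysis, homologous recombination, histones, tubulins, monocyte, granulocyte and stem cell genes, MLL fusion targets, FLT3 and STAT5 targets, interferon, NF-kappaB, antigen presentation, lysosome, metallothioneins, proteasome, drug transporters, and markers of erythroid, megakaryocyte, T and NK, B, epithelial and mesenchymal cells. Of the erythroid list only TFRC was tested, so it has no list p.

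Named genes followed a rule fixed beforehand. It took all genes of the study's title list, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 counts in the higher group and the same sign in all batches. From each list it took up to 4 called members with the largest change, fewer for secondary lists and for lists not past the threshold, or the most abundant member where none was called, and the most abundant member for markers of other cells. Further members are named where they were the few that fell, rose or were not called. COL1A1, FN1, ATF4, MALAT1, NEAT1, MIR22HG, BCL6, TP53INP2 and the examples of families and of FOXO targets were named after their values were seen.

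Alternatives were the batch block, DESeq2 1.42.0, RLE, upper-quartile and unscaled totals, no filter and a filter of at least 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) and with a mean FPKM of at least 1, and leaving out each library. Leaving out FKA replicates 2 and 3 together, and camera with RLE and upper-quartile factors, were added after seeing the data. The edgeR test was tested on simulated counts for FKA against control in 12947 genes. It recovered 36.7%, 68.8%, 93.9% and 96% of genes changed 1.5-, 2-, 4- and 8-fold, which were 18, 33, 46 and 48 genes. It also called 22 of 12751 unchanged genes (0.173%). These 22 were a larger share of all calls than the adjusted p threshold of 0.05 aims for. The share of false calls in the real data was not measured. In the simulation 200 genes were changed, as many higher as lower, a far smaller share than the 59.8% called in the real data. Recovery and scaling with so many changed genes were therefore not tested. In the list test on the same simulation, 0 of 20 unchanged lists and the raised list passed. Genes were simulated independently, so this does not test list p-values for genes that move together. In the real data the estimated correlation was 0.375 for the licensing list and 0.921 for the G2/M list.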

Results

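RNA sequencing measured messenger and non-coding transcripts in MV4;11, a human acute myeloid leukemia line that carries an internal tandem duplication of FLT3 and the MLL-AF4 fusion. 3 control libraries and 3 libraries from cells exposed to 10 µg/ml flavokawain A (FKA) for 48 h were compared. FKA is a chalcone of the kava plant. The labels assign each library to a batch, and each of the 3 batches holds 1 control and 1 FKA library. Total gene counts were 33759185, 36362421 and 35994015 in control replicates 1 to 3, and 30550819, 29971171 and 33183376 in FKA replicates 1 to 3. Between 17457 and 18409 of the 21857 listed genes had at least 1 count in a library. The first principal component of the log-scaled values held 82.7% of the variance and separated the groups, with controls between -72.26 and -61.51 and FKA libraries between 62.04 and 73.51.

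The comparison asks which transcripts differ after FKA, with the genes of the study's title (cell cycle genes, CDT1, p27 and the venetoclax target) first. CDT1, which loads the MCM helicase at replication origins, fell from 96.0 ± 25.2 to 2.06 ± 0.346 CPM (TMM-scaled counts relative to library size, mean ± SD, n = 3 per group), a log2 fold change of -5.54 (SE 0.234, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.38e-06). Within batches 1, 2 and 3 the log2 difference of CDT1 was -4.97, -5.77 and -5.71. The mRNA of CDKN1B, which encodes p27, stood at 106 ± 19.1 CPM in controls and 113 ± 9.22 CPM with FKA, and its difference of 0.09 on the log2 scale (SE 0.135, edgeR adjusted p = 0.582) was smaller than the spread between replicates. Its batch values were 0.54, -0.05 and -0.17, and without control replicate 1 its log2 fold change was -0.06. BCL2, the protein bound by venetoclax, fell from 304 ± 32.1 to 42.5 ± 6.41 CPM (log2 fold change -2.84, SE 0.138, edgeR adjusted p = 2.37e-06), whereas its relative MCL1 rose from 276 ± 13.9 to 400 ± 20.3 CPM (0.53, SE 0.0904, edgeR adjusted p = 0.000966).

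Of the 17 genes listed around that axis, 1 rose (2 with the batch block), 9 fell and 7 were not called. This list was taken from the study's own title and is not independent evidence of a direction. Besides CDT1 and BCL2, the fall included DTL (log2 fold change -4.76), the substrate receptor of the CUL4 ligase that degrades CDT1, the replication clamp PCNA (-1.89), cyclin E1 (CCNE1, -1.91), CDK4 (-1.36), CDK2 (-1.05) and the CDT1 inhibitor geminin (GMNN, -0.91). SKP2, the F-box protein that targets p27, fell slightly (-0.38, edgeR adjusted p = 0.00821), but missed the threshold with library totals as the only scaling (edgeR adjusted p = 0.0907). CUL4A (0.08), CUL4B (0.18), DDB1 (0.19), CDKN1A, which encodes p21 (0.03), and BCL2L1 (0.09) did not pass the test, though DDB1 (edgeR adjusted p = 0.011) and CUL4B (0.0398) did with library totals. Without control replicate 2 the value of CUL4A was -0.02, without control replicate 1 that of BCL2L1 was -0.04 and that of DDB1 0.28 (edgeR adjusted p = 0.0334), and without FKA replicate 3 that of CDKN1A was -0.17. CCND3 did not pass either (0.37, edgeR adjusted p = 0.102), but did so with the batch as a block (edgeR adjusted p = 0.0293). It also passed with library totals (0.53, edgeR adjusted p = 0.0427) and without control replicate 2 (0.54, edgeR adjusted p = 0.0305). The list as a whole had a camera adjusted p of 0.06, and passed in 5 of the 6 fits that leave out 1 library, with a range from 0.033 without FKA replicate 2 to 0.0647 without control replicate 2.

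**Figure D1:**
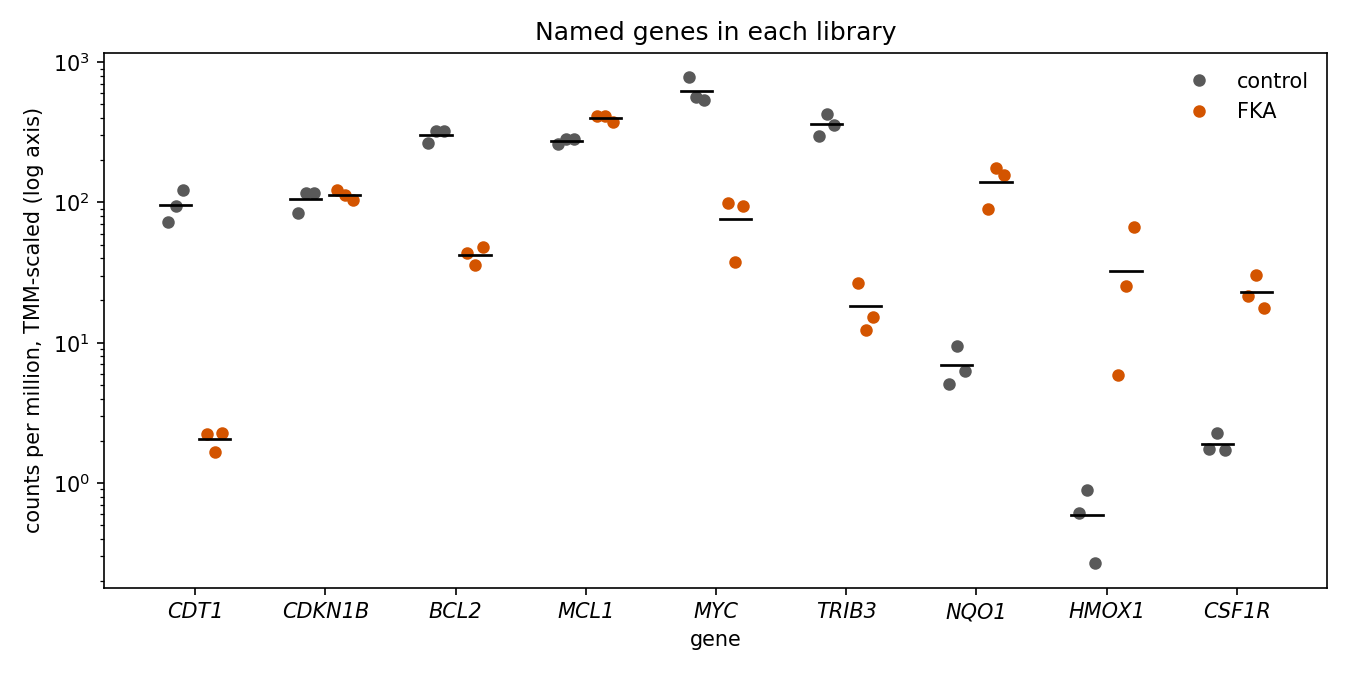
TMM-scaled CPM (log axis) of 9 named genes in each of the 3 control and 3 FKA libraries; points are libraries and black bars are group means. CDT1, BCL2, MYC and TRIB3 lie lower in all FKA libraries, MCL1, NQO1, HMOX1 and CSF1R lie higher, and the CDKN1B points of the groups overlap.

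Across the transcriptome, 8090 of 13531 tested genes (59.8%) passed edgeR's adjusted p threshold of 0.05, 3959 higher and 4131 lower with FKA. At least 2-fold changes were found in 3456 of them, 1604 higher and 1852 lower, and at least 8-fold changes in 135 higher and 333 lower genes. In all 3 batches 8057 of the called genes had a difference of one sign. The groups did not overlap in 7938 of the called genes, which forces one sign under any pairing, so that count is no separate check across batches. Over all tested genes the groups did not overlap in 9107, where chance gives 10%. Scaling by library totals alone raised the median log2 fold change of all genes by 0.16 and gave 4993 higher and 3282 lower genes, so that 60.3% of calls were higher, against 48.9% here. Changes below are relative to the TMM scaling. Collagen and fibronectin reads, which are described with the markers of other cell types, were high in FKA replicates 2 and 3. Without both of these libraries, a choice made after seeing the data, 4619 genes were called, 2020 higher and 2599 lower.

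The transcripts of DNA replication and cell division fell together. All 40 measured genes of replication licensing and the replication fork were lower (median log2 fold change -2.54, camera adjusted p = 6.8e-21, and adjusted p = 0.354 with an estimated correlation), among them MCM10 (64.2 to 0.293 CPM, log2 fold change -7.76), the helicase cofactor CDC45 (-7.47) and the licensing factor CDC6 (-5.74). All 28 G1/S genes driven by E2F factors were lower (median -3.33, camera adjusted p = 1.68e-16, and adjusted p = 0.354 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, went from 127 to 0.657 CPM (-7.59), and E2F2 (-7.18), the transcription factor MYBL2 (-7.06, and -7.67 without FKA replicate 2) and the exonuclease EXO1 (-7.00) fell as well. All 40 genes of G2 and mitosis were lower (median -3.75, camera adjusted p = 8.62e-16, and adjusted p = 0.759 with an estimated correlation). Examples were FOXM1 (-5.94), the transcription factor of this phase, UBE2C (-5.27, and -5.85 without FKA replicate 2), the kinesin KIF23 (-5.13) and the phosphatase CDC25C (-4.90). In each of these examples control replicate 1 lay well below the other controls, and the FKA libraries lay lower still. UBE2C had 13.4 CPM in control replicate 1 against 49.3 and 46.7 CPM in control replicates 2 and 3. Of 24 genes of homologous recombination and the Fanconi pathway, 23 fell and ATRIP did not pass (median -3.0, camera adjusted p = 6.35e-12, and adjusted p = 0.354 with an estimated correlation). Of 16 G1 cyclins, their kinases and partners, 12 fell and 4 were not called, of which CCND3 rose with the batch block (median -0.72, camera adjusted p = 0.000781, and adjusted p = 0.354 with an estimated correlation). Cyclin E2 (CCNE2, -3.91), MYC (-3.04), cyclin D2 (CCND2, -1.92) and CCNE1 led that fall. MYC, which is counted in this list, is also counted in the lists of ribosome biogenesis and of FLT3 and STAT5 targets. Adjusted over the list alone, the counts of members higher and lower in each fixed list equalled those adjusted over all genes, apart from the 3 lists where the former count is given.

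Genes of ribosome production and of amino acid stress also fell. MYC dropped from 628 ± 132 to 76.5 ± 33.8 CPM. In the list of MYC and ribosome biogenesis, which counts MYC itself, 27 of 28 genes were lower (median -1.44, camera adjusted p = 3.14e-08, and adjusted p = 0.759 with an estimated correlation). NME1 stood at -2.26, while the polyamine enzyme ODC1 was not called. Of 36 cytosolic ribosomal protein genes, 24 fell and 12 were not called (median -0.41, camera adjusted p = 0.00075, and adjusted p = 0.843 with an estimated correlation), with RPL5 at -0.99 and RPL3 at -0.95. Many processed pseudogenes copy these transcripts, so reads may have been divided among copies. Among 26 genes of the ATF4-driven integrated stress response, 22 fell and 4 did not pass, and 23 fell when adjusted over the list alone (median -1.47, camera adjusted p = 2.66e-07, and adjusted p = 0.759 with an estimated correlation). The pseudokinase TRIB3 went from 361 ± 64.3 to 18.2 ± 7.64 CPM (-4.31), STC2 changed by -3.93, the serine synthesis enzyme PSAT1 by -2.49 and the amino acid carrier SLC7A5 by -2.46, whereas ATF4 mRNA itself stood at -0.02 (edgeR adjusted p = 0.91). Without FKA replicate 1 the log2 fold changes of STC2, PSAT1 and SLC7A5 were -4.54, -3.90 and -3.17.

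Antioxidant and lysosomal transcripts rose, and so did most of the few tested histone transcripts. Of 23 NRF2 target genes, 19 rose, 3 fell and 1 was not called (median 1.34, camera adjusted p = 1.28e-05, and adjusted p = 0.705 with an estimated correlation). Heme oxygenase (HMOX1) went from 0.591 ± 0.314 to 32.6 ± 31.1 CPM (log2 fold change 5.77, SE 0.89, edgeR adjusted p = 0.000574), with 191, 807 and 2319 counts in the FKA libraries and a log2 fold change of 4.70 without FKA replicate 3. The quinone reductase NQO1 rose from 6.94 ± 2.32 to 141 ± 46 CPM (4.34), malic enzyme ME1 by 4.58 (5.23 without control replicate 2) and OSGIN1 by 3.71 (4.73 without control replicate 1). The members that fell were the cystine carrier SLC7A11 (-1.27), thioredoxin (TXN, -0.40) and BLVRB (-0.39). Of 27 autophagy and lysosome genes regulated by TFEB, 23 rose, 2 fell and 2 were not called, and 24 rose when adjusted over the list alone (median 1.06, camera adjusted p = 7.6e-08, and adjusted p = 0.354 with an estimated correlation). GABARAPL1, which builds autophagosomes, rose by 2.38 and the protease cathepsin D (CTSD) by 2.11, while TFEB (-0.61) and FLCN (-0.33) were the members that fell. Of 44 listed replication histone genes, 22 were in the data and 11 were tested, so most of the list has no test. Of these 11, 8 rose, 1 fell and 2 were not called (median 2.03, camera adjusted p = 0.012, and adjusted p = 0.759 with an estimated correlation). From low levels, H2AC6 rose by 3.66 (1.26 to 15.8 CPM) and H4C3 by 3.58 (0.358 to 4.26 CPM, and by 4.18 without control replicate 1), and H1-4 fell (-2.08). Histone genes of the same type are similar in sequence, so reads assigned to 1 member are uncertain. The list lost its call on log2(FPKM + 1) values (camera adjusted p = 0.322).

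**Figure D2:**
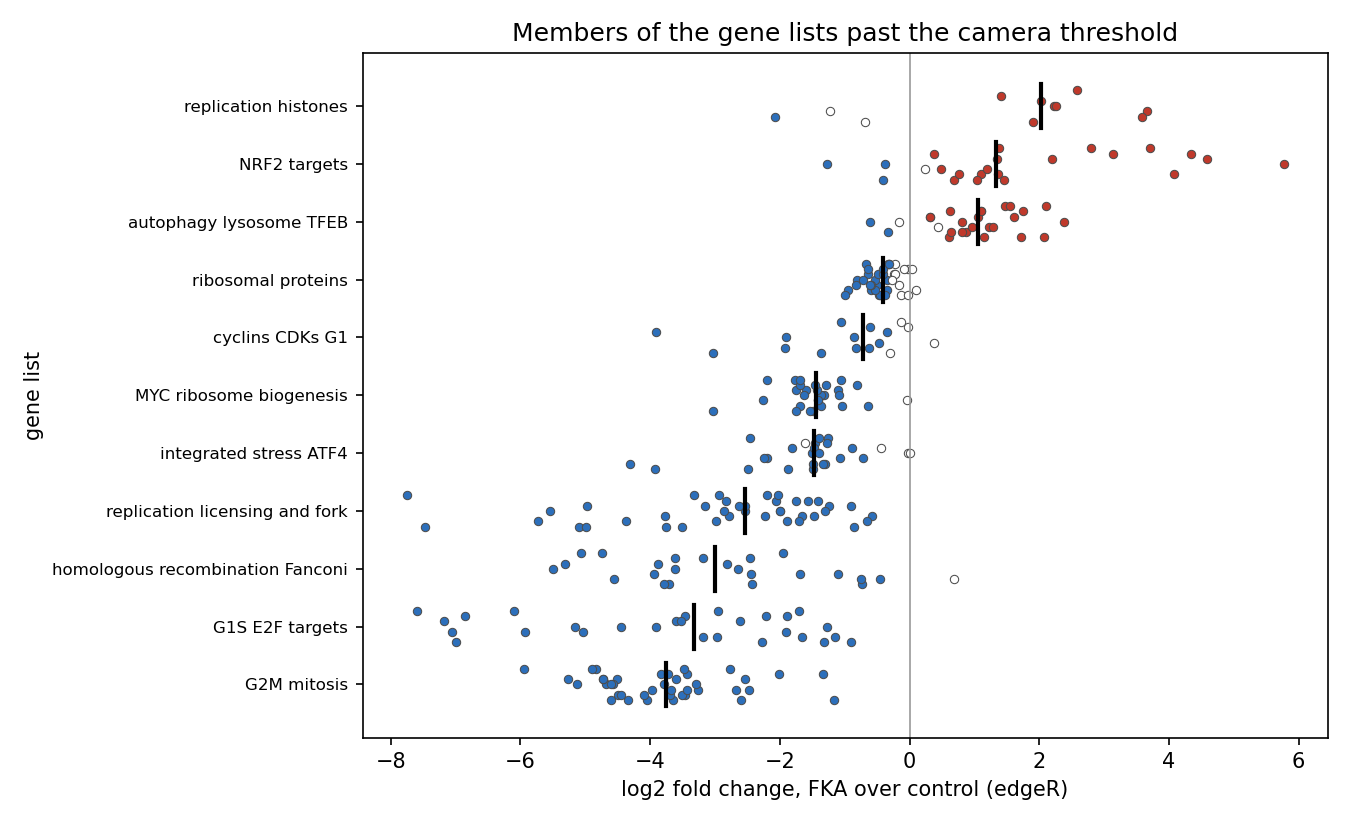
Log2 fold change (FKA over control, edgeR) of each measured member of the 11 gene lists past the camera threshold; red and blue points passed the test as higher and lower, open points did not, and black bars are list medians. In the lists of licensing, G1/S and G2/M genes all members are lower, and ribosomal proteins have a median of -0.41.

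Regulators of the cell cycle and of apoptosis went both ways. Of 14 CDK inhibitors and genes of cell cycle exit, 6 rose, 2 fell and 6 were not called (median 0.36, camera adjusted p = 0.176); BTG2 (1.61) and CCNG2 (1.26), both antiproliferative, rose. Of 18 genes of the CUL4 and SCF ubiquitin ligases, 2 rose, 10 fell and 6 were not called (median -0.31, camera adjusted p = 0.107), and the CDK-binding subunit CKS1B fell by 2.96. Of 26 p53 targets, 7 rose, 9 fell and 10 were not called (median 0.02, camera adjusted p = 0.933), with TP53INP1 at 2.78 and GADD45A at -2.21 (-2.89 without FKA replicate 3). Of 15 BCL2 family genes, 5 rose, 7 fell and 3 were not called (camera adjusted p = 0.751). The median of that family was 0.02, its mean -0.42 and its test pointed down. The BH3-only gene HRK fell with BCL2 (-2.68).

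Markers of myeloid identity and leukemia programs also split. Of 21 genes of monocyte and macrophage differentiation, 9 rose, 3 fell and 9 were not called (median 0.45, camera adjusted p = 0.107, and 0.036 without FKA replicate 1), and the receptor CSF1R went from 1.91 ± 0.307 to 23.2 ± 6.59 CPM (3.60), with CD86 at 2.46. Of 11 granulocyte precursor genes, 5 rose, 5 fell and 1 was not called (median -0.25, camera adjusted p = 0.87). Myeloperoxidase (MPO) dropped from 44.5 ± 21.1 to 1.06 ± 0.928 CPM (-5.36) and MS4A3 stood at -2.79, values that were -6.34 and -4.26 without FKA replicate 3. Of 12 stem and progenitor genes, 4 rose, 3 fell and 5 were not called (median -0.04, which was 0.12 with library totals, and a test pointing up with camera adjusted p = 0.751). The receptor KIT fell (-4.59, and -5.23 without FKA replicate 1) and the surface enzyme CD38 rose from 0.685 to 16.1 CPM (4.54). Of 21 MLL fusion targets, 4 rose, 9 fell and 8 were not called (median -0.29, camera adjusted p = 0.338), with MYB at -1.06 next to BCL2. Of 26 targets of FLT3, STAT5 and MAPK signaling, 6 rose, 9 fell and 11 were not called (median 0.12, mean -0.37, test down with camera adjusted p = 0.716), and the MAPK-responsive factor ETV4 fell (-4.10) with MYC.

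Stress, metabolic and immune lists did not pass camera either, though single members moved far. Of 20 endoplasmic reticulum chaperone genes, 1 rose, 9 fell and 10 were not called (median -0.38, camera adjusted p = 0.07, past the threshold in 4 of the 6 fits that leave out 1 library, with a range from 0.0309 without control replicate 2 to 0.146 without control replicate 1), with calreticulin (CALR) at -1.98 and HERPUD1 at -1.28. Of 17 heat shock genes, 4 rose (BAG3 by 1.32, HSPA1B by 1.27), 7 fell and 6 were not called (median -0.20, camera adjusted p = 0.751). Of 24 sterol synthesis genes, 9 rose (TM7SF2 by 2.45, SC5D by 1.28), 3 fell (5 with the batch block) and 12 were not called (median 0.18, camera adjusted p = 0.215). Of 12 fatty acid genes, 1 rose (ME1), 6 fell (FASN at -1.07) and 5 were not called (median -0.31, mean 0.03, test down with camera adjusted p = 0.237). Of 5 AHR targets, 1 rose (NQO1), 3 fell (CYP1B1 at -3.23) and 1 was not called (median -0.68, camera adjusted p = 0.604). Of 30 nuclear genes of oxidative phosphorylation, 5 rose (SDHC by 0.80), 10 fell (ATP5F1B at -0.60) and 15 were not called (median -0.04, which was 0.11 with library totals, camera adjusted p = 0.736). None of 13 mitochondrially encoded genes was called by edgeR or DESeq2, and 0 had an unadjusted edgeR p under 0.05 (median 0.02, camera adjusted p = 0.918). COX1 stood at 0.19 and passed with library totals (edgeR adjusted p = 0.0162). Of 25 glycolysis genes, 7 rose (PKM by 1.77), 8 fell (HK2 at -2.33) and 10 were not called (median -0.19, camera adjusted p = 0.751).

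Of 26 proteasome genes, 2 rose, 7 fell (PSMA6 at -0.91, PSMD14 at -0.78) and 17 were not called (median -0.11, which was above 0 with library totals, camera adjusted p = 0.4). Of 10 tubulin-related genes, 2 rose, 4 fell (TUBA1B at -1.66, TUBB at -1.31) and 4 were not called (median -0.30, camera adjusted p = 0.335). Of 6 metallothionein-related genes, 5 fell and the zinc exporter SLC30A1 was not called (median -2.56, camera adjusted p = 0.0969, and 0.0184 without control replicate 1), with MT1G at -5.30 (-6.04 without FKA replicate 3) and MT1X at -2.61. Tubulins, metallothioneins and HLA genes are families of similar sequence whose reads can be shared. Of 23 interferon genes, 10 rose (IFI6 by 3.05, IFIT3 by 2.07), 2 fell and 11 were not called (median 0.46, camera adjusted p = 0.176). Of 15 NF-kappaB genes, 7 rose, 4 fell (CCL5 at -3.51, TNFAIP3 at -3.12) and 4 were not called (median 0.32, mean -0.25, test up with camera adjusted p = 0.716). Of 12 antigen presentation genes, 3 rose (HLA-DMA by 1.80), 6 fell (PSMB8 at -1.55) and 3 were not called (median -0.25, camera adjusted p = 0.386). Of 4 drug transporters, 3 rose (ABCC2 by 1.10) and 1 fell (ABCC4 at -1.39), with a median of 0.69 and a camera adjusted p of 0.402.

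Markers of other cell types were measured in the same libraries. Of 5 tested mesenchymal genes none passed edgeR or DESeq2 and 2 had an unadjusted edgeR p under 0.05 (median 2.45, camera adjusted p = 0.751, and 0.036 without FKA replicate 1), and their levels differed between libraries of 1 group. COL1A1 had 75, 82 and 4 counts in control replicates 1 to 3 and 11, 417 and 449 in FKA replicates 1 to 3, and fibronectin (FN1) had 170, 168, 18, 19, 799 and 791 in that order. ACTA2, the most abundant marker of that list, stood at 29.6 ± 8.32 and 22.8 ± 2.3 CPM (-0.37, and -0.57 with edgeR adjusted p = 0.0171 without control replicate 3). Of 4 epithelial genes, 1 fell and 3 were not called (median 0.35, camera adjusted p = 0.918). That gene was KRT18 (-0.55, edgeR adjusted p = 0.019), which lost its edgeR call with library totals (adjusted p = 0.0827) and without control replicate 2 (0.0578), FKA replicate 1 (0.0543) or FKA replicate 3 (0.0598). Of 4 megakaryocyte genes, 2 rose and 2 were not called (median 0.89, camera adjusted p = 0.459), and NRGN (0.61, edgeR adjusted p = 0.08) passed with the batch block (edgeR adjusted p = 0.034) and in DESeq2 (adjusted p = 0.0496). Of 4 T and NK cell genes, 1 rose (CD4 by 0.93), 2 fell and 1 was not called, and 2 rose when adjusted over the list alone (median -0.18, camera adjusted p = 0.918). Of 3 B cell genes, 2 fell (PAX5 at -1.54) and 1 was not called (median -1.54, camera adjusted p = 0.205). TFRC, the single tested erythroid gene, stood at 0.15 (edgeR adjusted p = 0.652) and at -0.06 without control replicate 2 or FKA replicate 3.

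The largest single changes included genes with few or no reads in 1 group. KLHDC7B, CLGN and LRRC14B had 513, 411 and 152 counts over the controls and 0 with FKA. With a floor of 3 counts over the group they were 168-fold, 135-fold and 49.9-fold lower. The lower limits of their exact 95% counting intervals were 136-fold, 109-fold and 40.1-fold (counting error only). TERT, the catalytic subunit of telomerase, had 1175 counts in controls and 1 with FKA, a control to FKA ratio of 1160 with a 95% counting interval of 207 to 45700. The ratio was 213 (37.8 to 8440) for LINC00977 and 402 (172 to 1240) for the activin subunit gene INHBE. In the other direction the ratio was 0.0121 (0.00145 to 0.0443) for LOC105378339, 0.0141 (0.00289 to 0.0419) for LOC100996756 and 0.0263 (0.00845 to 0.0625) for C10orf105. For the genes from TERT to C10orf105 the fitted log2 fold changes moved when single libraries were left out, so ratios are given instead. LOC105378339 was not called on log2(FPKM + 1) (limma adjusted p = 0.0563). Among genes with more reads, the arrestin-like ARRDC3 rose from 1.41 ± 0.639 to 87.7 ± 26.3 CPM (5.94, SE 0.332, edgeR adjusted p = 4.53e-06), SPACA6 by 4.68, the protease gene ADAM28 by 4.43 (3.84 without FKA replicate 2) and LGI4 by 4.36.

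Of 41 lists tested, 11 passed camera with a preset correlation of 0.01, 8 lower and 3 higher, and 0 did so with an estimated correlation, where 5 had an unadjusted p under 0.05, while fry, which asks only whether members move one way, passed 23. The labels do not say whether libraries came from separate cultures, and p-values measure only the spread between these samples.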

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

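Leaving out FKA replicates 2 and 3 together, and camera with RLE and upper-quartile factors (11 lists each), were chosen after the data were seen. With the batch as a replicate block, 8289 genes were called, of which 7915 were also called without it in the same direction, and apart from CCND3 and NRGN no call of a named gene or list changed. In each alternative for the counts, 0 genes called there and in the reported fit had opposite directions. Of 84 counts of members per list, 28 moved by over 1.5 times without both FKA libraries, 19 on log2(FPKM + 0.1), 19 with a mean FPKM of at least 1, 18 with library totals, 17 on log2(FPKM + 1) and at most 10 under each other alternative. With all 6 libraries the number of genes called ran from 6846 on log2(FPKM + 1) with a mean FPKM of at least 1 to 8356 with DESeq2. On leaving out 1 library it ran from 7090 without control replicate 3 to 8193 without control replicate 1, and it fell to 4619 (2020 higher, 2599 lower, 1000 at least 2-fold higher) with 1 FKA library, whose spread is then assumed to be that of the controls. At least 2-fold changes numbered 1575 (735 higher, 840 lower) on log2(FPKM + 1), which shrinks changes of low genes, and 1545 (721, 824) with a mean FPKM of at least 1. On that filter KLHDC7B, CLGN, LRRC14B, LINC00977, LOC105378339, C10orf105, HRK, OSGIN1 and KIT gave no value, and LRRC14B, LOC105378339 and the lists of megakaryocyte, T and NK, B cell and epithelial markers gave none with at least 1 CPM in 3 libraries. For the lists below values are adjusted p, and the cause was not tested unless stated. With an estimated correlation 0 lists passed: licensing, G1/S, G1 cyclins, recombination and lysosome were at 0.354, NRF2 at 0.705, G2/M, ATF4, MYC and histones at 0.759 and ribosomal proteins at 0.843. Fry, which does not compare a list with other genes, passed 23 lists, among them the title list (0.000536), the ligases (0.000883), endoplasmic reticulum chaperones (0.0491), sterols (0.0165), AHR (0.0244), monocyte (0.021), stem cell (0.0296), FLT3 and STAT5 (0.0347), interferon (0.0165), antigen presentation (0.0195), metallothionein (0.021), megakaryocyte (0.0172) and B cell lists (0.00717), while ribosomal proteins missed it (0.0505) and heat shock (0.882) and granulocyte genes (0.838) turned direction. The title list passed with library totals (0.0481), on log2(FPKM + 1) (0.031) and without both FKA libraries (0.0136). On log2(FPKM + 1) metallothioneins passed (0.031) and histones did not (0.322). The p53 list turned direction with library totals (0.987), log2(FPKM + 1) (0.944) and without both FKA libraries (0.533), respiratory genes with library totals (0.862) and log2(FPKM + 1) (0.742), and mesenchymal markers without both FKA libraries (0.272). Leaving out each library gave ranges of 0.033 to 0.0647 for the title list, 0.569 to 0.907 for p53, 0.0309 to 0.146 for chaperones, 0.458 to 0.915 for mitochondrial genes, 0.036 to 0.273 for monocyte, 0.569 to 0.96 for granulocyte, 0.0184 to 0.117 for metallothionein, 0.733 to 0.992 for epithelial and 0.036 to 0.9 for mesenchymal lists. Log2 fold changes of genes that were not called turned sign within -0.06 to 0.16 (CDKN1B), -0.018 to 0.205 (CUL4A), -0.17 to 0.23 (CDKN1A), -0.043 to 0.179 (BCL2L1) and -0.057 to 0.521 (TFRC). CDKN1A was at -0.006 without a filter and, like BCL2L1 (-0.035), negative without both FKA libraries (-0.37). SKP2 lost its call on log2(FPKM + 1) (-0.20) too. Depth limits genes of few counts, for which ratios have wide counting intervals.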

Other observations

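Tests chosen after the result was seen were those of gene families, of the response in FKA replicate 1, of FKA, of batch and of a fixed ratio for the collagen reads, and of abundance and length for the long non-coding RNAs. For these tests 15 gene families were sorted by symbol without antisense and divergent genes. Some share genes with the fixed lists, such as KIF23 (kinesins and G2/M) and PSMA6 (proteasome), and are not independent of them. Of the 15 families, 10 passed camera and 5 did not: zinc fingers (ZNF, adjusted p = 0.98), solute carriers (0.591), RAB GTPases (0.165), SR splicing factors (0.243) and 37 proteasome subunits (0.087). Of those that passed, 6 are given here. Of 77 mitochondrial ribosomal protein genes 53 fell, 3 rose and 21 were not called (median log2 fold change -0.55), with MRPL3 at -1.49 and MRPS6 at 2.16. Of 21 nucleoporins 18 fell and 3 were not called (NUP88 at -1.49), of 18 aminoacyl-tRNA synthetases 13 fell and 5 were not called (IARS1 at -1.81), and of 8 subunits of the chaperonin CCT 7 fell and 1 was not called (CCT6A at -0.94). Of 24 snoRNA host genes 14 fell, 2 rose and 8 were not called (SNHG8 at -2.02). Of 16 vacuolar ATPase genes, which acidify lysosomes, 9 rose, 1 fell and 6 were not called (ATP6V0A1 by 1.38). Their camera adjusted p values were 1.22e-06, 2.8e-06, 0.000553, 0.00433, 0.00149 and 0.00513 in that order, and each was adjusted p = 0.433 with an estimated correlation. No median of these 6 families changed sign under the 4 scalings.

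Long non-coding RNAs tended to be higher with FKA. Of 1451 tested 504 rose and 269 fell (median 0.39), against 3304 and 3769 of 11603 protein-coding genes (median -0.03), and the odds of a call being higher were 2.14 times as large (Fisher's exact test across genes, which are not independent, two-sided p = 1.31e-22). Examples were the nuclear RNAs MALAT1 (65.6 ± 20 to 616 ± 78 CPM, n = 3) and NEAT1 (275 ± 6.07 to 1317 ± 143 CPM), and MIR22HG rose by 4.20 on the log2 scale. The tables argue against low abundance alone, and against gene length alone, as the whole cause. Of 10000 sets of protein-coding genes matched on abundance, 95% had medians of 0.086 to 0.189. Of sets matched on length 95% had medians of -0.109 to -0.029, and both ranges lie below 0.39. Sets matched on both were not drawn, so a joint effect was not tested. The difference of the medians, 0.42 or more over 4 scalings, decides nothing on library scaling, because 1 factor per library moves both classes of genes alike. That FKA raises these RNAs remains a hypothesis, and antisense members may hold reads of partner genes, which was not tested because the use of strand is not stated.

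The collagen and fibronectin reads were high in FKA replicates 2 and 3 and not in FKA replicate 1. The 9 matrix genes of the fixed mesenchymal list summed to 51.9 and 48.2 CPM in the former, to 0.963 CPM in the latter and to 10.4, 8.49 and 0.773 CPM in the controls, so 1 FKA library lay below 2 of the controls. These sums argue against the labelled batch as the whole cause, because the 2 libraries of batches 1, 2 and 3 differed by 10.8, 6.11 and 62.4 times. Among the controls, 10.4 and 8.49 against 0.773 CPM were measured without FKA, and in batch 1 the control was the higher library. These values argue against FKA as the whole cause of the differences between libraries. Whether FKA added to the reads in FKA replicates 2 and 3, or trace RNA of fibroblast-like cells did, cannot be told apart. A second fibroblast list was 1.17 and 1.32 times higher in FKA replicates 2 and 3 than in FKA replicate 1. TIMP1, IGFBP7, COL6A3 and TPM2, abundant in every library here, made up most of that list. Among the 4 libraries with at least 50 COL1A1 counts the ratio to COL1A1 differed by 1.29 times for FN1, 1.62 times for COL3A1 and 2.09 times for COL1A2, which leaves 1 outside source open. As far as 1 library can show, such RNA alone does not account for the response at large: of genes called without FKA replicate 1 and 1 control, 96.9%, 97.9% and 99.1% (control 1, 2 or 3 left out) differed between these 2 libraries in the called direction, where 50% would if FKA replicate 1 were like a control.

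ARRDC3, BCL6 (2.18 ± 0.438 to 33.7 ± 18.9 CPM, n = 3) and TP53INP2 (51.3 ± 6.74 to 520 ± 49.8 CPM), counted as targets of FOXO transcription factors, were among the far risers. The smallest of their log2 fold changes was 3.34 over 4 scalings, which moved the median of all genes by up to 0.16. The choice among these scalings is thus too small to make such rises. Because the 3 genes were picked as far risers, that outcome was set in advance and is no evidence for another cause. More active FOXO factors are a hypothesis that made a prediction for 20 other FOXO targets: 13 rose, 4 fell and 3 were not called, with a median log2 fold change of 0.72 (camera p = 0.00628, and p = 0.178 with an estimated correlation). YPEL5 (1.71), SESN3 (1.70) and PINK1 (1.66) rose, but TXNIP fell (-1.11), IRS2 was at -0.07, and FOXO activity itself was not measured. Other targets seen before that test are given as examples and are not a full tally. CCNG2 rose (1.26), CDKN1B (0.09) and BCL2L11 (0.13) were not called and GADD45A fell (-2.21, and -2.89 without FKA replicate 3). The hypothesis is left open. With library totals the median of the 20 targets was 0.88.

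With 3 against 3 libraries there are 10 splits, which cannot give a share under 0.05. In the FKA split 8090 genes were called, and 3456 of at least 2-fold, and 493 list members, where the highest of the others was 0 each time in edgeR (11 to 271 genes at an unadjusted p under 0.05, and at most 2 called by DESeq2), so 1 split reached the real count. For lists past camera 10 of the 10 splits reached the real count of 11, and the highest of the others was 19. Each of the 9 others sets 2 libraries of 1 treatment beside 1 of the other, so it keeps part of the FKA difference and adds the rest to the spread.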
